A study of Mus musculus with 24 samples.

How the data were processed

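RNA of eGFP-positive cells sorted from E15.5 mouse embryos was measured in 24 libraries, 22 of pancreas and a pair of hypothalamus. Per the labels' protocols, tissue was dissociated with trypsin, cells were sorted by eGFP, 50 ng of RNA with an integrity number above 7.5 went into strand-specific libraries after ribosomal RNA depletion, and these were sequenced on an Illumina NovaSeq. Per the labels, embryos of both sexes were pooled, though Xist runs from 0.434 to 1010 CPM of total over the libraries. Per the submitters' processing notes, the authors used cutadapt 2.10, STAR 2.7.8a and featureCounts 2.0.2 with build GRCm38.p6, and the strand setting of the counting and the handling of duplicates are not given in the sources used here. The deposited table of counts holds whole-number counts per gene made by the authors with those tools, with no normalization. The deposited FPKM table holds FPKM values, scaled for gene length and library total, that the authors made from the same reads, and FPKM rebuilt from the counts had a median relative difference of 0.00015 from it, with 97% of values within 1%. The deposited read statistics give the percent of duplicate reads, of aligned reads and of properly paired reads that the sequencing core exported per library, with tools not given in the sources used here.

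The table holds 40173 genes. Gene names that a spreadsheet had turned into dates (26) were matched back by gene identifier, 31 repeated symbols were given a suffix, and 1 line of column totals was left out. Groups follow the titles. The genotype field gives Ngn3eGFP/eGFP for libraries titled control and Ngn3eGFP/+ for those titled mutant, and the titles were kept. Control ND 1 has a mixed genotype by its description and was not used downstream by the submitters, so it was left out of the groups and tried as a control ND library in an alternative. The hypothalamic libraries, 1 per title, were given as values with 95% Poisson intervals.

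Counts of 21 libraries in 6 groups were fitted in 1 model with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1): low counts were removed with filterByExpr, which kept 23630 genes (58.8% of genes and at least 99.91% of the counts of each library), libraries were scaled with TMM, dispersions were estimated robustly, and contrasts were tested with quasi-likelihood F-tests. Adjusted p-values are from the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. There were 9 comparisons: genotype by title on each diet, HFD or LPD against ND within each title, and the difference of each diet change between titles. Folds are those of edgeR, errors beside log2 values are standard errors, and CPM values of the 21 libraries are scaled by TMM. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

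A set of 28 gene lists (668 symbols, of which 4 are missing from the table) was written before the data were examined, as were the groups, the comparisons, the rule for named genes and a list of alternatives. The lists cover hormones, endocrine transcription factors, regulated secretion, glucose sensing, duct and trunk, Notch, cell cycle, cell cycle exit, acinar cells, mesenchyme, endothelium, blood and immune cells, neural crest and glia, hypothalamic neurons, amino acid response, protein folding, nuclear and mitochondrial respiratory genes, fatty acid oxidation, lipid synthesis, glycolysis and hypoxia, ribosomal proteins, genes that dissociation induces, imprinted genes, antioxidant genes, chromatin regulators, insulin and mTOR signalling, and male-linked genes. Each list was tested with camera at a preset correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation and with fry. The genes that the text names are, for each comparison, the 6 largest and 6 smallest log2 fold changes among passing genes with a mean of at least 5 CPM, no overlap and an established name, up to 3 members of smallest adjusted p in each list that moved, and Neurog3, Ins1, Ins2, Gcg, Sst, Ghrl, Neurod1, Sox9, Hes1 and Mki67 throughout. Where fewer than 5 genes passed, up to 5 of smallest p were taken. The text names a part of them.

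The alternatives chosen then were DESeq2 size factors in edgeR, DESeq2 1.42.0, no filter on low counts, limma on log2(FPKM + 1), only the compared libraries in the fit, replicate number as a block, the mixed library as a control, and leaving out each library. Alternatives added after the values were seen left out the ND libraries of over 70% duplicates or the titled mutant libraries with hormone counts, took the Gm26917 share or library numbers of 25 or above as a covariate, left Gm26917 out of the counts, or summed mutant LPD 1 and LPD 2. The median log2 fold change of all genes was -0.232 by limma on FPKM and -0.111 with the replicate block for genotype on ND, where edgeR gave 0.010. By limma on FPKM it was 0.211 for LPD and 0.140 for HFD in titled mutant (0.057 and -0.008 by edgeR), and 0.185 and 0.203 for the HFD and LPD differences between titles (-0.047 and -0.003 by edgeR).

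Depth gave the spread between libraries more weight than counting error. For genes of at least 100 counts, pairs of libraries of a group differed by 2.44 to 70.2 times the variance of counting (median 16.7 of 27 pairs), and the closest pairs were mutant LPD 1 and LPD 2 (2.44) and mutant HFD 1 and HFD 2 (3.4). If the libraries of these pairs are not independent, the spread of those groups is understated. They were counted as separate libraries, and only mutant LPD 1 and LPD 2 were also summed. Whether replicate numbers pair the libraries of different groups was checked by correlating their departures from the group means, and only genotype on HFD had all 3 pairs above 0.1 (0.21 to 0.57), so libraries were treated as unpaired and the paired value for that comparison is 1374 genes. On simulated data with no change, edgeR called 0 of 23042 genes in each of the 9 comparisons. All simulations drew genes independently, with 1 spread per gene for all libraries. They lack the unequal libraries and linked genes of the data, so their rates may not carry over. With genes changed in simulation for HFD in titled control, edgeR recovered 32.3% at 2-fold and 62.2% at 4-fold with 3 false calls, and DESeq2 36% and 67% with 30 false calls.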

Results

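The study asked how the diet of the mother acts on islet progenitors of the mouse embryo. RNA of eGFP-positive cells sorted at E15.5 was sequenced in 24 libraries. In this mouse line eGFP stands in place of the coding part of Neurog3 (Ngn3), the transcription factor that commits pancreatic progenitors to the endocrine lineage. Dams aged 6 weeks ate a normal diet (ND), a high-fat diet (HFD) or a low-protein diet (LPD) for 2 weeks before mating and until the embryos were collected. By title, 3 control and 4 mutant pancreatic libraries came from ND, 3 control and 3 mutant from HFD, and 4 control and 4 mutant from LPD. A further ND library of mixed genotype and a pair of hypothalamic libraries, 1 control and 1 mutant, were given as values with no test. Total counts per library ran from 17922240 to 44688814. Whether replicates came from separate litters is not given in the sources used here, so each p-value measures the spread between these libraries.

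Neurog3, the targeted gene, was read first in every library as CPM of total counts, before TMM scaling. The gene (ENSMUSG00000044312.4) lies on chromosome 10 from 62133090 to 62134763 in build GRCm38.p6, with its coding sequence from 62133463 to 62134104, so untranslated parts could still be counted where eGFP replaces the coding part. On ND, Neurog3 stood at 183, 212 and 205 in the 3 libraries titled control and at 9.68, 6.71, 6.69 and 10.2 in the 4 titled mutant. On HFD it stood at 117, 99.0 and 121 in the 3 titled control and at 11.2, 6.13 and 7.85 in the 3 titled mutant. On LPD it stood at 276, 180, 193 and 144 in the 4 titled control and at 19.5, 23.2, 8.23 and 6.19 in the 4 titled mutant. The mixed library held 40.8, and the hypothalamic libraries held 2.75 (95% Poisson interval 2.17 to 3.43) when titled control and 0.568 (0.331 to 0.909) when titled mutant. The genotype field of the labels gives Ngn3eGFP/eGFP for libraries titled control and Ngn3eGFP/+ for those titled mutant, while the design text gives eGFP/eGFP embryos cells that have not yet committed. All 10 libraries titled control lay above all 11 titled mutant in Neurog3 (98.95 to 276 against 6.13 to 23.2), so the values go with the titles and against the genotype field. Groups are named by title throughout.

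**Figure D1:**
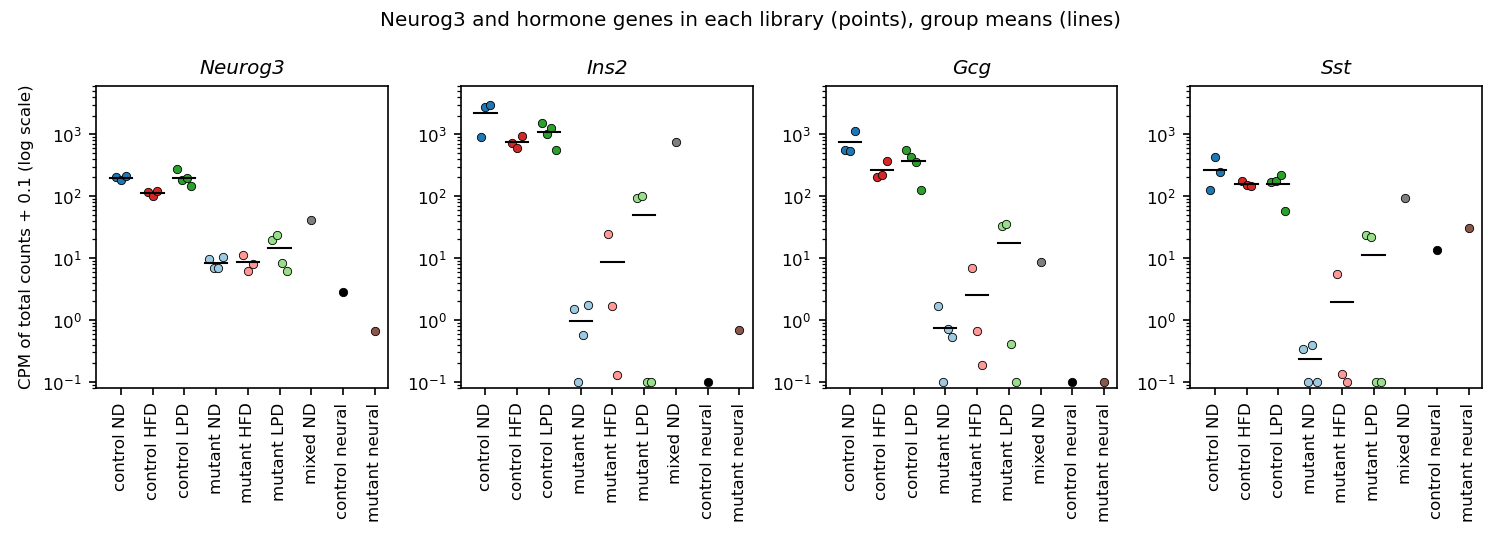
CPM of total counts plus 0.1 on a log axis for Neurog3, Ins2, Gcg and Sst, with 1 point per library and a line at each group mean. Neurog3 means were 200, 112 and 198 in titled control on ND, HFD and LPD and 8.31, 8.39 and 14.3 in titled mutant.

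Some libraries stood apart in quality. Gm26917, a long non-coding RNA on chromosome 17 from 39843013 to 39846341 in a region of ribosomal RNA sequence, took 66.95% of counts in mutant ND 2, 33.4% in mutant ND 3 and 32.7% in control ND 2, and 9.21 to 18.7% in the other 18 libraries of the groups. The same 3 libraries had 79.4, 72.2 and 79.1% duplicate reads, against 37.7 to 65.5% in the other 18. The mixed library, outside the groups, had 56.83% on Gm26917 and 80.2% duplicates, and the hypothalamic libraries had 82.3% (titled mutant) and 77.5% duplicates (titled control). Mutant ND 2 detected 17861 genes, the fewest of the 21. Mitochondrial transcripts took 0.282 to 0.786% of counts in control ND and 1.04 to 1.60% in control HFD. In titled mutant they took 0.707, 0.034, 0.282 and 0.579% in ND 1 to ND 4, 0.851 to 1.02% on HFD and 0.991 to 1.36% on LPD. The library numbers of the labels ran from 5 to 22 for HFD and LPD, while 5 of the 7 ND libraries had numbers of 25 or above, the exceptions being control ND 4 (8) and mutant ND 1 (10).

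**Figure D2:**
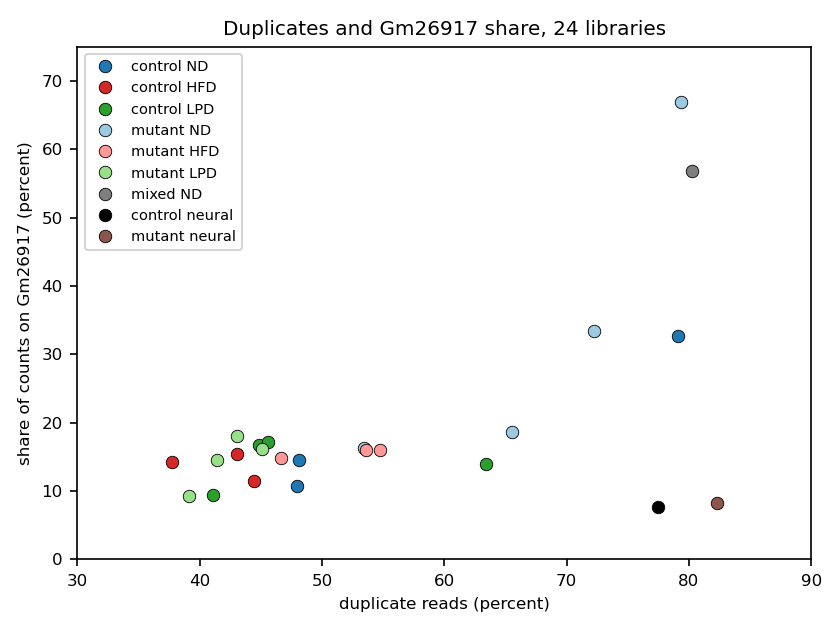
Percent of duplicate reads against percent of counts on Gm26917, 1 point per library, coloured by group, for all 24 libraries. Control ND 2, mutant ND 2 and mutant ND 3 lie at 79.1, 79.4 and 72.2% duplicates.

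What lower Neurog3 goes with in eGFP-positive cells was asked on each diet, and on ND the endocrine program was lower in titled mutant. Neurog3 was 16.5-fold lower, at 11.2 TMM-scaled CPM ± 4.33 (SD, n = 4) against 181 ± 17.7 (SD, n = 3; log2 -4.05, SE 0.39, adjusted p = 4.14e-07). All 10 islet hormone genes fell, among them Ins2 (0.869 CPM ± 0.714 against 2093 ± 1211), Gcg (0.649 ± 0.584 against 653 ± 231) and Sst (0.145 ± 0.179 against 259 ± 193), and Ins1 and Ins2 are paralogs whose reads are hard to part. Of the 28 transcription factors of endocrine differentiation 27 fell, among them Neurod1 (0.0266 CPM ± 0.0532 against 97.2 ± 12.9), Mlxipl, a glucose-responsive factor (log2 -4.58, SE 0.36), and Tox3 (log2 -3.74, SE 0.29), while Hhex did not pass (log2 0.09, SE 0.23). Of 31 genes of regulated secretion 29 fell, among them Unc13a, which primes vesicles for release (log2 -3.40, SE 0.26), and the granule protein Ptprn (log2 -5.20, SE 0.42). Of 16 genes of glucose sensing 15 fell, among them the incretin receptors Glp1r (log2 -5.97, SE 0.46) and Gipr (log2 -5.27, SE 0.50). Adjusted over the list alone these counts stayed at 10, 27, 29 and 15. The LIM factor Lhx1 (24.3 CPM ± 1.54, n = 3) and the cadherin Cdhr1 (28.3 ± 9.48, n = 3) had no count in any of the 4 titled mutant libraries, at least 758-fold and at least 902-fold lower against a floor of 3 counts over the group. The 4 lists passed the list test (adjusted p = 1.9e-07, 1.2e-29, 1.2e-32 and 9.2e-21), at adjusted p = 0.27 for hormones and 0.08 for each of the others with an estimated correlation.

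Most cell cycle genes and a part of the acinar and ribosomal genes rose in titled mutant on ND. Of 36 genes of DNA replication and mitosis 33 rose (34 adjusted over the list alone), among them the spindle checkpoint kinase gene Bub1b (133 CPM ± 9.80, n = 4, against 61.5 ± 5.86, n = 3), Cdc20 (log2 1.43, SE 0.20) and the proliferation marker Mki67 (613 CPM ± 32.3 against 344 ± 82.8). Of 25 acinar genes 12 rose (13 adjusted over the list alone), among them the acinar regulators Rbpjl (329 CPM ± 50.3 against 117 ± 25.2), Bhlha15 (log2 1.44, SE 0.23) and Nr5a2 (log2 1.17, SE 0.19). Of 45 ribosomal protein genes, a family with many pseudogenes that make single members uncertain, 28 rose (33 adjusted over the list alone), and of 25 genes of glycolysis and hypoxia 15 rose (15 adjusted over the list alone), among them Ldha (log2 1.23, SE 0.20). The genes of the hedgehog-binding proteins Hhip (log2 2.37, SE 0.33) and Gas1 (log2 2.09, SE 0.25) rose as well. Median log2 fold changes were 0.94, 1.21, 0.69 and 0.69 for the cell cycle, acinar, ribosomal and glycolysis lists (adjusted p = 6.9e-19, 4.2e-07, 4.2e-11 and 2.4e-06), and adjusted p = 0.20, 0.35, 0.35 and 0.29 with an estimated correlation. Endothelial markers had a median of 0.93 (2 of 14 rose, 2 adjusted over the list alone; adjusted p = 0.002, and 0.66 with an estimated correlation).

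In all, 6381 of 23630 genes changed with genotype on ND, 3234 up and 3147 down, and 5138 of them had values without overlap. Chance gives this for 5.71% of genes not chosen by their p. Genes chosen by a small p in the same libraries mostly separate, so here and in the other comparisons this adds no separate support. The share without overlap over all tested genes was not counted. With only the ND libraries in the fit 2279 genes changed (780 up and 1499 down), and limma on FPKM gave 401 up and 4282 down. With a term for library numbers of 25 or above 6498 genes changed.

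On HFD the same question gave 1366 genes, 33 higher and 1333 lower in titled mutant (1365 without overlap, 10% by chance for genes not chosen by p). Neurog3 was 12.4-fold lower (8.51 CPM ± 2.61, n = 3, against 106 ± 18.7, n = 3; adjusted p = 1.96e-05). Of the 10 hormone genes 7 fell (10 adjusted over the list alone), among them Gcg (2.46 CPM ± 3.71 against 250 ± 104), while Ins2 (8.63 ± 13.6 against 702 ± 206; adjusted p = 0.084) did not pass. Of the 28 endocrine transcription factors 27 fell (27 adjusted over the list alone), among them Irx2 (log2 -6.35, SE 1.12) and Neurod1 (log2 -6.50, SE 1.38). Of 31 secretion genes 26 fell (30 adjusted over the list alone), Unc13a at log2 -2.94 (SE 0.29), and of 16 glucose-sensing genes 12 fell (15 adjusted over the list alone), Cacna1c, an L-type calcium channel, at log2 -2.50 (SE 0.27). The imprinted gene Peg10 was 16.8-fold lower (26.1 CPM ± 13.6 against 439 ± 164). The ciliogenesis factor Foxj1 (log2 1.59, SE 0.40) and the claudin Cldn2 (log2 1.52, SE 0.31) rose. Of the cell cycle genes 1, Cdc6, rose (log2 0.66, SE 0.18; 0 of 36 adjusted over the list alone) and of the acinar genes 0 of 25 passed by edgeR (0 adjusted over the list alone), with list medians of 0.36 and 0.41 (adjusted p = 2.3e-08 and 0.0012, and 0.52 and 0.60 with an estimated correlation).

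The endocrine factor, secretion and glucose-sensing lists held with an estimated correlation on HFD (adjusted p = 0.021 each) and on LPD (adjusted p = 0.028 each), and those 6 were the list calls of all 9 comparisons that did. By fry 13, 7 and 13 of 28 lists passed for genotype on ND, HFD and LPD. With HFD against ND 10 passed in titled control and 5 in titled mutant. For the hormones on HFD it was adjusted p = 2.2e-09, and 0.21 with an estimated correlation. The HFD genotype count was 3590 (1208 up and 2382 down) with only the HFD libraries in the fit, so the low number of higher genes depends on the fit. It was 841 by limma on FPKM and 2155 without the 3 ND libraries of over 70% duplicates, and 1374 with replicate number as a block, 1222 of them among the 1366. With a term for library numbers of 25 or above it was 1379.

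On LPD 3683 genes changed with genotype, 1234 up and 2449 down in titled mutant (3438 without overlap, 2.86% by chance for genes not chosen by p). Neurog3 was 12.4-fold lower (14 CPM ± 8.64, n = 4, against 174 ± 31, n = 4; adjusted p = 1.50e-06). Of the 10 hormone genes 7 fell (10 adjusted over the list alone), Cck at log2 -4.92 (SE 0.61), while Ins1 (31.6 CPM ± 36.5 against 593 ± 210; adjusted p = 0.0675) and Sst (11.3 ± 13 against 139 ± 67.1; adjusted p = 0.0691) did not pass. Of 28 endocrine factors 27 fell (27 adjusted over the list alone), among them Nkx2-2 (log2 -2.08, SE 0.17) and the serotonergic factor Fev (log2 -4.80, SE 0.90). Nhlh1, a basic helix-loop-helix gene outside the list, also fell (log2 -4.98, SE 0.61). Of 31 secretion genes 30 fell (30 down and 1 up adjusted over the list alone) and of 16 glucose-sensing genes 14 fell (15 adjusted over the list alone). Of 36 cell cycle genes 25 rose (32 adjusted over the list alone), Mki67 at 819 CPM ± 95 against 493 ± 143, and of 25 acinar genes 13 rose (17 adjusted over the list alone), the trypsin inhibitor Spink1 at 40.1 CPM ± 7.18 against 17.9 ± 7.12 and Rbpjl at log2 1.13 (SE 0.21). The imprinted RNA H19 rose (3503 CPM ± 695 against 1740 ± 521). Acinar and cell cycle lists had medians of 1.14 and 0.61 (adjusted p = 1.2e-10 and 4.8e-13, and 0.26 for both with an estimated correlation). Endothelial markers and mitochondrially encoded genes had medians of 0.56 each (0 of 14 and 0 of 13 passing by edgeR, 0 and 0 adjusted over the list alone; adjusted p = 0.015 and 0.016, and 0.69 and 0.68 with an estimated correlation).

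Titled mutant LPD 1 and LPD 2 held Ins2 at 96.5 and 101 CPM, and mutant HFD 1 at 24.3 CPM, while mutant LPD 3 and LPD 4 had no Ins2 count. Without these 3 libraries the LPD genotype count was 1804. It was 2375 by limma on FPKM (228 up and 2147 down), 6321 without the 3 ND libraries of over 70% duplicates, 5962 with the Gm26917 share as a covariate, and 3874 with a term for library numbers of 25 or above.

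Across the 3 diets 1253 genes were lower and 29 higher in titled mutant every time, and 0 genes took opposite directions. The 29 cannot exceed the 33 genes higher on HFD, a number that depends on the fit, as given above. ND and HFD shared 1276 lower genes (177.5 by chance) and 32 higher (4.5 by chance). ND and LPD shared 2094 lower (326.2 by chance) and 1052 higher (168.9 by chance).

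Whether HFD alters the transcriptome was asked within each title. In titled control, a part of the acinar genes rose and a few endocrine genes fell on HFD against ND. Of 25 acinar genes 12 rose (21 adjusted over the list alone), among them Spink1 (37.4 CPM ± 6.35, n = 3, against 9.81 ± 1.22, n = 3; log2 1.93, SE 0.28), Rbpjl (353 ± 39.4 against 117 ± 25.2) and the lipase-related Pnliprp1 (9237 ± 893 against 2456 ± 494), and members with close paralogs are uncertain. Of 28 endocrine factors 3 fell (4 adjusted over the list alone), the beta-cell factor Mafa (44.4 CPM ± 9.54 against 164 ± 81.8), Pdx1 (126 ± 3.86 against 207 ± 27.3) and Nkx2-2 (log2 -0.72, SE 0.19), while Neurog3 (106 ± 18.7 against 181 ± 17.7; adjusted p = 0.276) and Ins2 (log2 -1.58, SE 1.59) did not pass. Of 31 secretion genes 0 passed by edgeR (5 fell adjusted over the list alone), and of 16 glucose-sensing genes 2 fell, Trpm5 (log2 -1.19, SE 0.28) and the imprinted Nnat (log2 -1.63, SE 0.44), with 1 up and 6 down adjusted over the list alone. The incretin hormone gene Gip was lower (3.17 CPM ± 0.783 against 28.7 ± 21.9) and so was Npy (5.00 ± 2.83 against 28.8 ± 15.4). The acinar median was 1.66 and the endocrine factor, secretion and glucose-sensing medians were -0.78, -0.86 and -0.91 (adjusted p = 2e-25, 6.4e-06, 1.1e-06 and 3.9e-05), and adjusted p = 0.12, 0.38, 0.38 and 0.37 with an estimated correlation. Beside these, blood and immune markers had a median of -1.04 (adjusted p = 0.00012, and 0.38 with an estimated correlation), 1 of 17 falling (1 adjusted over the list alone), Hbb-y at least 23-fold lower against a floor of 3 counts over the group.

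**Figure D3:**
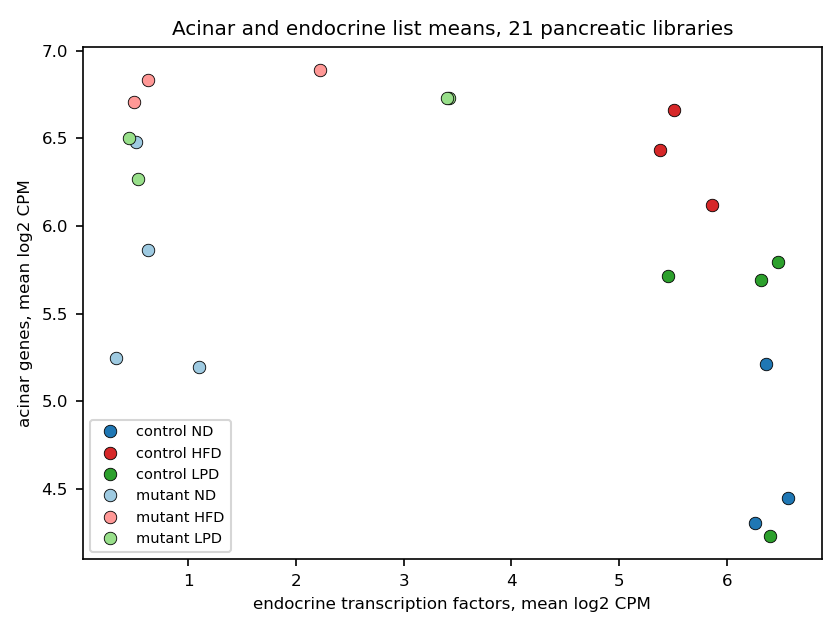
Mean log2 CPM of the endocrine transcription factor list (horizontal) against that of the acinar list (vertical), 1 point per library, for the 21 pancreatic libraries coloured by group. Control LPD 1 lies at 4.23 on the acinar axis, and the other 3 control LPD libraries at 5.69 to 5.79.

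Some ribosomal, cell cycle, glycolysis, amino acid response and folding genes also rose on HFD in titled control. Of 45 ribosomal genes 18 rose (39 adjusted over the list alone) and of 36 cell cycle genes 9 rose (27 adjusted over the list alone), among them Rrm2 (118 CPM ± 10.4, n = 3, against 54.6 ± 7.88, n = 3) and Mki67 (651 ± 64.1 against 344 ± 82.8). Of 25 glycolysis and hypoxia genes 12 rose (16 up and 1 down adjusted over the list alone), Car9, a carbonic anhydrase, 3.61-fold (130 CPM ± 8.65 against 35.8 ± 6.89) and Egln3, a prolyl hydroxylase, 5.21-fold. Of 25 tested genes of the amino acid response 6 rose and 1 fell (10 up and 1 down adjusted over the list alone), with asparagine synthetase Asns at 205 CPM ± 15 against 73.2 ± 1.55 and Sesn2 down at log2 -0.79 (SE 0.21). Of 23 genes of protein folding in the endoplasmic reticulum 4 rose (8 adjusted over the list alone), Herpud1 at 159 CPM ± 25.2 against 69.7 ± 6.47. The Notch target Hes1 rose 2.66-fold, metallothionein Mt1 4.09-fold, and the retinol-binding protein Rbp2 7.53-fold (10.9 CPM ± 6.94 against 1.45 ± 0.471). Medians were 0.74, 0.64, 0.67, 0.61 and 0.30 for these 5 lists (adjusted p = 8e-24, 2e-16, 2.1e-11, 5.7e-06 and 8.5e-07), and adjusted p = 0.23, 0.29, 0.23, 0.37 and 0.35 with an estimated correlation. The 25 genes that tissue dissociation induces had a median of 0.48, 4 rising (9 adjusted over the list alone), among them Atf3 (212 CPM ± 64.4 against 83.0 ± 3.41; list adjusted p = 3.9e-05, and 0.35 with an estimated correlation), and the 13 mitochondrially encoded genes a median of 1.08, mt-Nd2 and mt-Nd6 rising (4 adjusted over the list alone; adjusted p = 1.9e-05, and 0.37 with an estimated correlation).

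In titled control 924 genes changed with HFD, 733 up and 191 down (921 without overlap, 10% by chance for genes not chosen by p). With DESeq2 size factors the split was 648 up and 290 down, and limma on FPKM gave 252 genes, 95 up and 157 down. The count was 77 without control ND 2, 262 without control ND 3, and 192, 344 and 448 without control HFD 1, HFD 2 or HFD 3. It was 318 without the 3 titled mutant libraries with hormone counts, 2248 by DESeq2, 1792 with only these libraries in the fit, 1563 with replicate number as a block and 2624 with the Gm26917 share as a covariate. With a term for library numbers of 25 or above, which sets control ND 4 apart from control ND 2 and ND 3, it was 233 (229 up and 4 down), 192 of them among the 924. Without control ND 2, 36 of the 44 changed genes of this comparison named in the text or weighed for it no longer passed.

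In titled mutant, some acinar, folding and immediate early genes rose and a few connective tissue genes fell on HFD, in a comparison that few alternatives keep. Of 25 acinar genes 3 rose (5 adjusted over the list alone), Spink1 (44.1 CPM ± 2.77, n = 3, against 13.6 ± 3.86, n = 4), colipase Clps (1788 ± 115 against 523 ± 259) and Pnliprp1 (log2 1.10, SE 0.28). Of 23 folding genes 5 rose (13 adjusted over the list alone), among them Herpud1 (194 CPM ± 33.5 against 103 ± 17), Dnajc3 (log2 0.61, SE 0.12) and Dnajb9 (log2 1.04, SE 0.24). Of the 25 genes that dissociation induces 7 rose (13 adjusted over the list alone), Atf3 3.37-fold (230 CPM ± 60.1 against 67.9 ± 27.6), Egr1 3.02-fold and Klf6 2.45-fold. Of 13 mitochondrially encoded genes 3 rose (10 adjusted over the list alone), mt-Nd2, mt-Nd5 and mt-Nd6 (577 CPM ± 41.0, 1220 ± 103 and 165 ± 23.8 against 222 ± 109, 554 ± 240 and 76.1 ± 22.2). The cartilage collagen Col2a1 fell 6.40-fold (11.9 CPM ± 2.64 against 76.9 ± 62.1), as did Basp1 (log2 -2.70, SE 0.61) and the neurotrophin receptor Ngfr (log2 -2.86, SE 0.73), with wide spread among the ND libraries. Of 23 mesenchyme genes 2 fell, Sparc (log2 -0.81, SE 0.16) and Vim (log2 -0.65, SE 0.14), and 13 did adjusted over the list alone. Medians of the acinar, folding, dissociation, mitochondrial and mesenchyme lists were 0.73, 0.39, 0.58, 1.21 and -1.64 (adjusted p = 1.3e-08, 2.8e-08, 1.9e-07, 2.6e-08 and 3.8e-08), at adjusted p = 0.39 each with an estimated correlation. Beside these, blood and immune markers had a median of -1.37 (0 of 17 passing by edgeR, 3 down adjusted over the list alone; adjusted p = 3.5e-05). Endothelial markers had a median of -0.66 (0 of 14 passing, 0 adjusted over the list alone; adjusted p = 0.013). Each was at adjusted p = 0.65 with an estimated correlation. Notch3 was lower (log2 -1.14, SE 0.19), and Neurog3 (8.51 ± 2.61 against 11.2 ± 4.33; adjusted p = 0.601) did not pass.

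In titled mutant 676 genes changed with HFD, 227 up and 449 down (651 without overlap, 5.71% by chance for genes not chosen by p). The count was 42, 45 and 72 without mutant HFD 3, HFD 2 or HFD 1, 393, 1275 and 1835 without mutant ND 3, ND 4 or ND 1. It was 312 without the 3 ND libraries of over 70% duplicates, 24 without the titled mutant libraries with hormone counts, 0 with only these libraries in the fit, 60 with replicate number as a block, 418 without a filter, 6 by limma on FPKM and 2349 by DESeq2. With a term for library numbers of 25 or above, which sets mutant ND 1 apart from the other ND libraries, it was 12, 10 of them among the 676, and none of the 29 changed genes of this comparison named in the text or weighed for it passed.

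HFD changed 167 genes the same way in both titles, in comparisons that share no library: 96 rose (7 by chance) and 71 fell (3.6 by chance), with 0 in opposite directions. The chance numbers assume independent comparisons, while control and mutant HFD libraries of the same number were correlated (0.21 to 0.57) and most ND libraries of each title have late numbers. Tmed11, of a family that carries cargo between the endoplasmic reticulum and Golgi, rose in titled control (3.16 CPM ± 1.05, n = 3, against 0.287 ± 0.0917, n = 3) and in titled mutant (2.87 ± 0.382, n = 3, against 0.136 ± 0.115, n = 4). Spink1, Herpud1, Dnajc3, Atf3 and Egln3 were among those that rose. The retinaldehyde dehydrogenase Aldh1a1 rose by log2 1.97 (SE 0.27) and 1.21 (SE 0.25), and the amino acid transporter Slc38a2 by log2 0.61 (SE 0.13) and 0.55 (SE 0.12). Among those that fell were the actin-binding Dbn1 (log2 -1.15, SE 0.21, and -1.30, SE 0.20), the protease Capn2 (log2 -0.71, SE 0.12, and -0.70, SE 0.11) and glutamine synthetase Glul (log2 -0.88, SE 0.19, and -0.81, SE 0.18). These genes were chosen after their values were seen, apart from those that the rule names.

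Whether the HFD change differs between titles gave 0 genes by edgeR (1677 at an unadjusted p under 0.05, smallest adjusted p = 0.639), 0 by limma on FPKM and 13 by DESeq2. The smallest unadjusted p-values, none passing, were those of Glp1r (log2 2.98, SE 0.60), Gas1 (log2 -1.52, SE 0.35), Mpzl2 (log2 -1.45, SE 0.33), Tlx1 (log2 -6.80, SE 1.58) and Rab44 (log2 -2.57, SE 0.60). In simulated data of this size the test recovered 3% of genes changed 2-fold and 54.1% of those changed 4-fold, over 23000 genes. Of 28 lists 11 passed the list test with the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.50) or by fry.

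LPD was compared with ND in the same way. In titled control no gene passed by edgeR (1553 at an unadjusted p under 0.05, smallest adjusted p = 0.612), while DESeq2 gave 2 and limma on FPKM 0. The genes of smallest unadjusted p were Pfkp, a phosphofructokinase (20.8 CPM ± 3.33, n = 4, against 12.7 ± 1.62, n = 3), Rgs11 (45.6 ± 14.2 against 23.2 ± 2.26), Il22ra1 (28.2 ± 10.5 against 11.4 ± 5.33) and Chmp4c (61.6 ± 12.6 against 38.9 ± 6.04), none passing. Of 25 acinar genes 0 passed by edgeR (12 up adjusted over the list alone), with Rbpjl at 209 CPM ± 77.6 against 117 ± 25.2 and Nr5a2 at 166 ± 46.9 against 102 ± 28.3. Of 25 amino acid response genes 0 passed by edgeR (6 up adjusted over the list alone), with Asns at 138 CPM ± 51.9 against 73.2 ± 1.55, Shmt2 at log2 0.88 (SE 0.22) and Cth at log2 0.95 (SE 0.26), and of 25 glycolysis and hypoxia genes 0 passed (8 up adjusted over the list alone), with Egln3 at log2 1.52 (SE 0.35). Neurog3 was at 174 CPM ± 31 against 181 ± 17.7. Medians of the acinar, amino acid and glycolysis lists were 0.79, 0.57 and 0.38 (adjusted p = 2.1e-11, 1.8e-08 and 5.9e-09), at adjusted p = 0.42 each with an estimated correlation. Ribosomal and cell cycle lists had medians of 0.43 and 0.37 (adjusted p = 3e-17 and 2.8e-11, and 0.42 for both with an estimated correlation). Blood and immune markers had a median of -0.91 (adjusted p = 6.2e-08, and 0.42 with an estimated correlation) and mesenchyme markers of -0.62 (adjusted p = 4e-05, and 0.48 with an estimated correlation). In these 4 lists 0 genes passed by edgeR (0 adjusted over the list alone). Duct and trunk genes had a median of 0.19 and endothelial markers of 0.28. In all, 16 of 28 lists passed the list test with the preset correlation, 11 up and 5 down, and 0 with an estimated correlation. The lists given here are a part of those. By fry 0 of 28 lists passed (smallest adjusted p = 0.21). Without control LPD 1, whose acinar mean lay apart from the other 3, 310 genes passed. With a term for library numbers of 25 or above 0 passed. Simulated data of this size gave 24.7% of genes changed 2-fold and 61.9% of those changed 4-fold, over 23038 genes.

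In titled mutant, a few mitochondrial transcripts rose on LPD, in a comparison that few alternatives keep. Of 13 mitochondrially encoded protein genes 3 rose (11 adjusted over the list alone), mt-Nd6 (194 CPM ± 29.7, n = 4, against 76.1 ± 22.2, n = 4), mt-Nd2 (545 ± 40.9 against 222 ± 109) and mt-Nd5 (1291 ± 148 against 554 ± 240), and so did the ribosomal RNA mt-Rnr2 (3130 ± 882 against 661 ± 333). Rbp2 rose 4.84-fold (9.44 CPM ± 2.60 against 1.81 ± 1.31), Spink1 2.93-fold and the calcium channel Cacna1d 1.81-fold. Eif2s3y, a Y-linked gene, was at 16 CPM ± 3.40 against 8.16 ± 2.67 (adjusted p = 0.0357). Ngfr (log2 -2.85, SE 0.65), Basp1 (log2 -2.46, SE 0.54) and Col2a1 (log2 -2.10, SE 0.39) fell. Of 10 hormone genes 0 passed by edgeR (10 up adjusted over the list alone) and of 28 endocrine factors 1 rose, Mlxipl (log2 1.45, SE 0.31; 13 up and 1 down adjusted over the list alone). Those lists had medians of 4.74 and 1.63 (adjusted p = 0.0034 and 0.00067, and 0.68 for both with an estimated correlation), which turned to -1.77 and -0.41 (adjusted p = 0.0084 for both) without the 3 titled mutant libraries with hormone counts. The mitochondrial list had a median of 1.28 (adjusted p = 6.7e-09, and 0.65 with an estimated correlation), and of 0.79 (adjusted p = 2e-09) without the ND libraries of over 70% duplicates. Mutant ND 2 and ND 3, high in Gm26917, had the lowest mitochondrial shares of titled mutant (0.034 and 0.282%). Mesenchyme markers had a median of -0.98 (0 of 23 passing by edgeR, 8 down adjusted over the list alone; adjusted p = 9.2e-07, and 0.65 with an estimated correlation). Blood and immune markers had a median of -0.92 (0 of 17 passing, 0 adjusted over the list alone; adjusted p = 0.00067, and 0.68 with an estimated correlation). Acinar genes had a median of 0.48, 1 rising (7 adjusted over the list alone; adjusted p = 3.5e-05, and 0.68 with an estimated correlation). In all, 14 of 28 lists passed the list test with the preset correlation, 11 up and 3 down, and 0 with an estimated correlation. The lists given here are a part of those. By fry 2 of 28 lists passed.

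In titled mutant 249 genes changed with LPD, 97 up and 152 down (232 without overlap, 2.86% by chance for genes not chosen by p). The count was 4, 3, 12 and 92 without mutant LPD 1, LPD 2, LPD 3 or LPD 4, 2439, 83, 18 and 1458 without mutant ND 1, ND 2, ND 3 or ND 4. It was 0 without the ND libraries of over 70% duplicates, 0 without those with hormone counts and 0 with only these libraries in the fit. It was 124 without a filter, 17 by limma on FPKM, 2289 by DESeq2, 6 with replicate number as a block, 8 with the Gm26917 share as a covariate, 4 with mutant LPD 1 and LPD 2 summed, and 0 with a term for library numbers of 25 or above. The HFD and LPD comparisons of a title share their ND libraries.

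Whether the LPD change differs between titles gave 0 genes by edgeR (1383 at an unadjusted p under 0.05, smallest adjusted p = 0.832), 0 by DESeq2 and 0 by limma on FPKM. The smallest unadjusted p-values, none passing, included those of Glp1r (log2 2.45, SE 0.56), Xkr5 (log2 -1.49, SE 0.34) and Erich3, which had no count in mutant ND. Of 28 lists 13 passed the list test with the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.45) or by fry. Simulated data of this size gave 14.4% of genes changed 2-fold and 50.5% of those changed 4-fold, over 22979 genes.

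**Figure D4:**
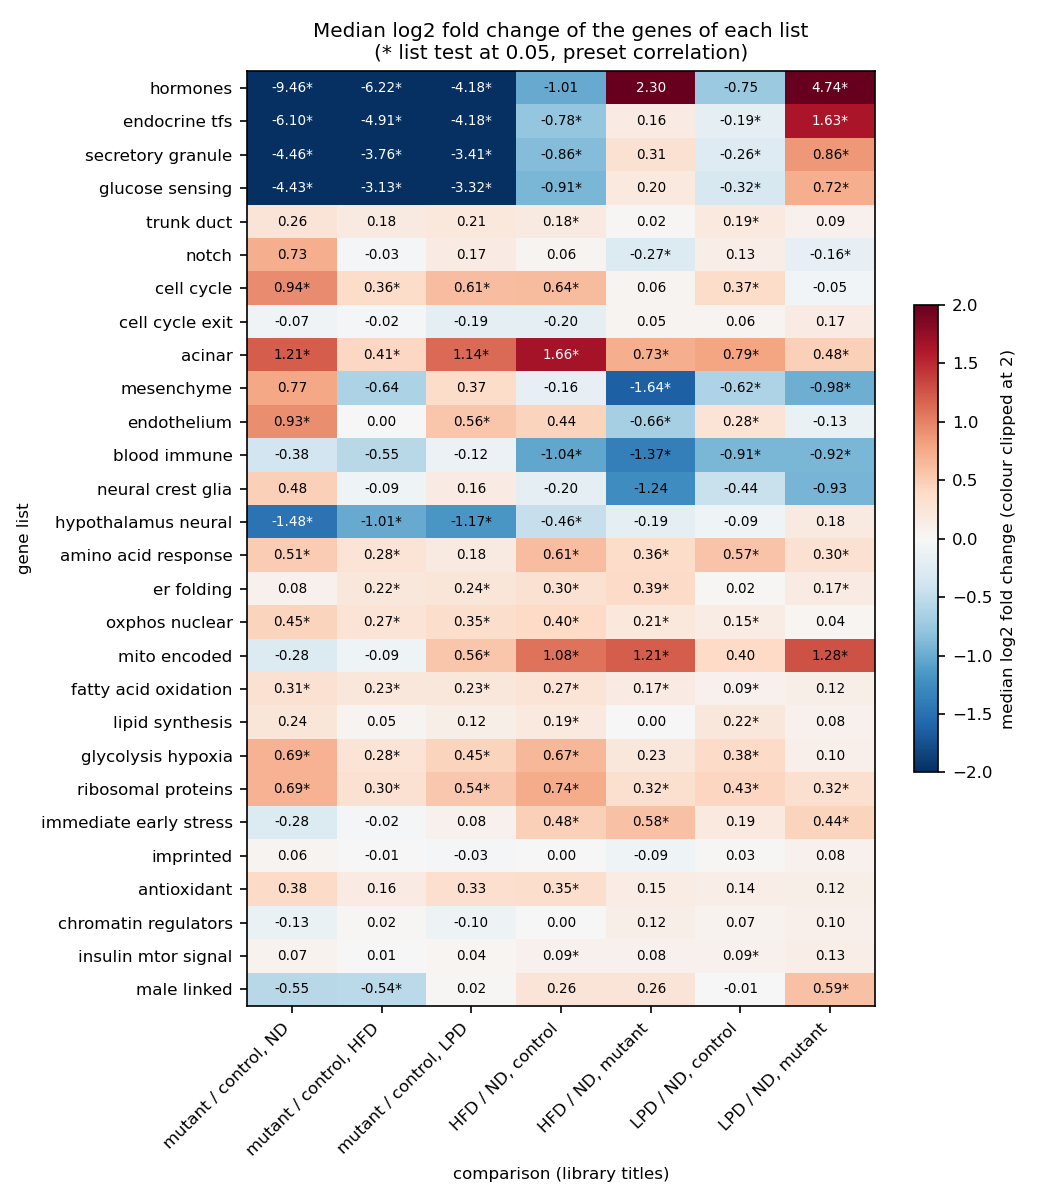
Median log2 fold change of each of 28 gene lists (vertical axis) in 7 comparisons (horizontal axis), with colour clipped at 2 and a star where the list test passed with the preset correlation. Acinar medians run from 0.41 to 1.66 over the 7 columns, and endocrine factor medians are -6.10, -4.91 and -4.18 with genotype on ND, HFD and LPD.

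The hypothalamic pair, 1 library per title and so with no test, was read beside the pancreatic ND libraries. Of the neural list, 31 genes had a median 6.18 log2 above pancreatic ND. Nkx2-1, a hypothalamic regional factor, was at 252 CPM (246 to 257) in titled mutant and 285 (279 to 291) in titled control, and 0 in pancreatic ND. Pomc, the proopiomelanocortin gene, was at 8.15 (7.16 to 9.24) against 38.8 (36.6 to 41.2), and Sst at 30.2 (28.3 to 32.3) against 13.4 (12.1 to 14.8). Ins1 and Gcg had no count in either, which allows up to 0.123 and 0.132 CPM. Xist, expressed from the inactive X, was at 0.434 in titled mutant and 912 in titled control, beside Ddx3y, a Y-linked gene, at 52.8 and 23.7, although the labels give both sexes as pooled. Parenthesised intervals are 95% Poisson intervals, which cover counting error only and take reads as independent, so they are too narrow at 82.3 and 77.5% duplicates if duplicates were counted.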

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

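Of the tests in this part, those of duplicates and of the acinar and duct medians in titled control on HFD, and those of the endocrine transcripts in titled mutant libraries, were chosen after the result was seen, as were the alternatives that leave out libraries by duplicates or hormone counts, sum libraries or take library numbers as a covariate.

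The titled control LPD libraries differed among themselves in endocrine and acinar genes. Control LPD 4 lay far below the other 3 in the endocrine lists, with mean log2 CPM of 5.45 for endocrine transcription factors (6.32 to 6.48 in the others), 5.43 for secretion (6.39 to 6.52) and 4.74 for glucose sensing (5.66 to 5.85), and with Neurod1 at 48.9 TMM-scaled CPM (102 to 112.5). Its mitochondrial transcripts took 1.11% of counts (0.65 to 0.682% in the others). Control LPD 1 lay far below in acinar genes (4.23 against 5.69 to 5.79) and endothelial genes (2.89 against 4.05 to 4.17) and had the highest alignment rate (96.94% against 94.9 to 95.14%). In mutant ND 2 the fatty acid oxidation mean was 3.83 (4.68 to 4.83 in the others) and the ribosomal mean 8.25 (8.87 to 8.99), and mutant ND 1 held Neurod1 at 0.106 TMM-scaled CPM with 0 in the other 3. In mutant LPD 3 mitochondrial transcripts took 1.36% (0.991 to 1.04%) and the endothelial mean was 3.63 (4.66 to 4.71), and mutant LPD 2 detected 28970 genes (29497 to 29541). These are 14 of 135 sets of values in groups of 4 libraries, where chance alone sets a library apart in about 1 in 20 sets.

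List medians of the diet changes differed between the titles with the preset correlation, but no list passed with an estimated correlation (smallest adjusted p = 0.50 for HFD and 0.45 for LPD) or by fry (0.35 and 0.39), and no single gene passed by edgeR (1677 genes at an unadjusted p under 0.05 for HFD and 1383 for LPD; 13 and 0 by DESeq2, 0 and 0 by limma on FPKM). For HFD the median log2 difference, titled mutant minus titled control, was 3.05 for hormones, 1.32 for endocrine factors, 1.17 for secretion, 0.89 for glucose sensing, -0.46 for Notch, -0.59 for cell cycle, -0.81 for acinar, -1.57 for mesenchyme, -0.89 for endothelium, -0.42 for glycolysis and -0.42 for ribosomal genes. For LPD it was 5.37 for hormones, 1.88 for endocrine factors, 1.17 for secretion, 0.96 for glucose sensing, -0.38 for Notch, -0.37 for cell cycle, -0.40 for mesenchyme, -0.30 for endothelium, 0.85 for mitochondrially encoded genes, -0.26 for glycolysis, -0.12 for ribosomal genes, 0.27 for genes that dissociation induces and 0.60 for male-linked genes. Without the 3 titled mutant libraries with hormone counts the LPD medians were -1.26 for hormones, -0.21 for endocrine factors and -0.13 for secretion (adjusted p = 0.12, 0.35 and 0.83), so those differences rest on mutant LPD 1 and LPD 2, and the HFD medians were 0.37 for hormones (adjusted p = 0.22) and 0.38 for endocrine factors (adjusted p = 2.4e-05).

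The ND library of mixed genotype, outside the groups, held Alb at 5868 CPM of total, while the 21 libraries of the groups held 2.40 to 329.3. Albumin is a liver transcript, and no explanation was tested.

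In titled control on HFD 12 of 25 acinar genes rose and 3 of 28 endocrine factors fell, and the list calls were lost with an estimated correlation (adjusted p = 0.12 and 0.38). High duplicate rates as the whole cause are argued against by lists fixed beforehand, whose medians without the 3 ND libraries of over 70% duplicates were 1.52 for acinar genes and -0.73 for endocrine factors (1.66 and -0.78 with them). Of the 924 genes 490 still passed then, while without control ND 2 alone 77 genes passed, without control HFD 1 192 and without control ND 3 262. Of the 3 libraries of high duplicates only control ND 2 is in this comparison. Mutant ND 2 and ND 3 act on it only through the filter, scaling and spread shared in the fit. The 490 genes are therefore no evidence against duplicates, and the cause of the drops was not tested. Fewer endocrine cells, if they raised every other cell type alike, would not put acinar genes above duct and trunk genes. The acinar median lay 1.48 above the duct and trunk median (SE 0.20, from resampling list members and not libraries). That premise is uncertain, since for genotype on ND, where the endocrine lists fell, a part of the acinar genes rose while duct genes were mixed. Fewer endocrine cells therefore stay open. A larger share of cells with the titled mutant profile may add to the acinar and endocrine change. Of the 686 genes called both here and for genotype on LPD, which shares no library, 100% had the same sign. Of the acinar genes, 19 of 25 had a higher log2 fold change here than for genotype on ND. Both changes are taken against the same control ND libraries, so this count only sets control HFD above mutant ND. Mutant ND includes ND 2 and ND 3, with high duplicates, and the count does not weigh against such a share. A change of the diet itself and the library numbers stay open, and with numbers of 25 or above as a covariate 233 genes passed.

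Endocrine transcripts in titled mutant LPD 1, LPD 2 and HFD 1 were weighed next. In LPD 1 and LPD 2 the excess over LPD 3 and LPD 4 came to a median of 8.53% of the titled control level over 39 endocrine genes (5.02 to 16.2%), and to 8.49% for Neurog3, a ratio of 1. In HFD 1 the median was 3.63% and Neurog3 3.92%. Endocrine differentiation without Neurog3 was taken to need Neurog3 to lag behind, and the ratio of 1 showed no such lag. Untranslated parts of Neurog3 could still be counted from the eGFP allele, so the ratio cannot decide this. Cells of the titled control kind in the sorted sample are a candidate source. Carry-over of RNA or library from a titled control library cannot be told apart from such cells, since each predicts a uniform share. In LPD 1 and LPD 2, 39 of 39 genes lay within a factor of 2 of the median. In HFD 1 the shares ran from 0.69% for Gast, at 0.0451 CPM there, to 6.86% for Irx1.

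Genes changed with HFD in both titles (167) were set against library number. The ND libraries of low number, control ND 4 and mutant ND 1, lay at 0.44 and 0.38 of the way from the later ND libraries to the HFD libraries over 292 genes chosen without them. Those genes were chosen by the gap between the libraries that set both ends, which draws a library left out toward HFD. No position without an effect of library number was computed, so late against early libraries cannot be told apart from the diet. Over the 167 genes control ND 4 and mutant ND 1 lay at 0.23 and 0.17, under the bound of 0.25 set beforehand against an effect of library number. These genes were called with both libraries among ND, which draws the position toward 0, so the bound was wrong for them. Without the ND libraries of high duplicates the median ratio of fold changes over the 167 genes was 0.89 in each title. These genes were called with those libraries among ND, and calling favours genes whose other ND libraries also differ from HFD. That keeps the ratio high, so it cannot tell whether high duplicates are the whole cause.

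Other splits of the same libraries were counted for each comparison. For genotype on ND the real split (6381 genes) was the highest of 35. The next, 5698, set the 3 control ND libraries with mutant ND 1 against mutant ND 2, ND 3 and ND 4. For genotype on LPD the real split gave 3683 against 0 at most in the others of 35. A share of 1 in 35 is the smallest that these splits can give, and it was not corrected over the comparisons. The splits also take libraries as independent, which is uncertain for mutant LPD 1 and LPD 2. The rank of the real split therefore cannot exclude chance by itself. For LPD in titled mutant the real split was again 1 of 35 (249 against 5), which has the same limits. There 4 genes passed with mutant LPD 1 and LPD 2 summed, 0 with library numbers of 25 or above as a covariate and 0 without the ND libraries of over 70% duplicates. For genotype on HFD (1366 against 0 at most in the others) and HFD in titled control (924 against 0) the 10 splits are too few for a share under 0.05. For HFD in titled mutant chance cannot be excluded: 3 of 35 splits gave as many as the real 676, the highest, 1649, setting the late-numbered mutant ND 2, ND 3 and ND 4 against mutant ND 1 and the HFD libraries, and with library numbers of 25 or above as a covariate 12 genes passed. For LPD in titled control (0 genes, 35 of 35 splits) the highest, 835, set control LPD 1 with the ND libraries against LPD 2, LPD 3 and LPD 4, a structure of the samples. For the differences between titles (0 genes) 30 of 30 splits gave as many, with 0 at most for HFD and 6 for LPD.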

How the results depend on the processing

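The alternatives that leave out the ND libraries of over 70% duplicates or the titled mutant libraries with hormone counts, that take the Gm26917 share or library numbers of 25 or above as a covariate, that leave Gm26917 out, or that sum mutant LPD 1 and LPD 2 were chosen after the data were seen. No named gene that passed in the main fit or in the alternative reversed its direction. Genes passing in neither were not compared in direction. Named genes were not read with only the compared libraries in the fit or with the mixed library as a control. The balance of calls turned over by limma on FPKM for HFD in titled control (733 up and 191 down to 95 and 157), HFD in titled mutant (227 and 449 to 5 and 1) and LPD in titled mutant (97 and 152 to 15 and 2), and for LPD in titled mutant with the replicate block (5 and 1), with mutant LPD 1 and LPD 2 summed (3 and 1) or without any of its LPD libraries in turn. For genotype on ND, near even at 3234 up and 3147 down, it turned over under several alternatives, among them DESeq2 size factors (2734 and 3600) and limma on FPKM (401 and 4282). The hormone and endocrine factor lists reversed for LPD in titled mutant, from medians of 4.74 and 1.63 to -1.77 and -0.41 without the titled mutant libraries with hormone counts. Of 184 counts of changed genes under alternatives 129 stayed within 1.5 times the main count, 38 were lower and 17 higher. Of 166 counts of lists called 150 stayed, 15 were lower and 1 higher. Of 5451 values of named genes 4634 kept their side of the threshold, 769 no longer passed and 48 newly passed. Counts that left that range were, by DESeq2, 2248 for HFD in titled control, 2349 for HFD and 2289 for LPD in titled mutant, 2 for LPD in titled control and 13 for the HFD difference between titles. By limma on FPKM they were 841 and 2375 for genotype on HFD and LPD, 252 for HFD in titled control, and 6 and 17 for HFD and LPD in titled mutant. With only the compared libraries in the fit, which leaves fewer samples, they were 2279 and 3590 for genotype on ND and HFD, 1792 for HFD in titled control and 0 for HFD and LPD in titled mutant. Without a filter they were 418 and 124 for HFD and LPD in titled mutant. With the replicate block they were 1563 for HFD in titled control, 60 for HFD and 6 for LPD in titled mutant, and the block moved no other count out of that range. Without the ND libraries of over 70% duplicates they were 2155 and 6321 for genotype on HFD and LPD, and 312 and 0 for HFD and LPD in titled mutant. Without the titled mutant libraries with hormone counts they were 1804 for genotype on LPD, 318 for HFD in titled control, and 24 and 0 for HFD and LPD in titled mutant. With the Gm26917 share as a covariate they were 5962 for genotype on LPD, 2624 for HFD in titled control and 8 for LPD in titled mutant. With library numbers of 25 or above as a covariate they were 233 for HFD in titled control, and 12 and 0 for HFD and LPD in titled mutant, and with mutant LPD 1 and LPD 2 summed 4 for LPD in titled mutant. Leaving out 1 library gave 4687 to 7068 genes for genotype on ND, 963 to 1187 on HFD and 2590 to 4332 on LPD, 77 (without control ND 2) to 1009 (without control ND 4) for HFD in titled control, 0 to 310 (without control LPD 1) for LPD in titled control, 42 (without mutant HFD 3) to 1835 (without mutant ND 1) for HFD in titled mutant, 3 (without mutant LPD 2) to 2439 (without mutant ND 1) for LPD in titled mutant, and 0 to 0 for each difference between titles. Where fewer samples are not the reason, the cause was not tested. Limma on FPKM scaled by library total and without TMM. Its median over all genes moved for genotype on ND and for HFD and LPD in titled mutant, as given with the methods. Its up and down counts in those comparisons carry that shift. In the hypothalamic pair a pseudocount of 2 in place of 0.5 moved the log2 difference of Neurog3 from -1.60 to -0.89 and of Ins2 from 1.14 to 0.38. In simulated data, with independent genes and even libraries, 24.7% of 2-fold changes were found for LPD in titled control. For the HFD and LPD differences between titles it was 3% and 14.4%.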

Other observations

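No test in this part was chosen after the result was seen. Imprinted, Notch and duct genes moved with genotype in a mixed way. On ND, of 27 imprinted genes 6 rose and 8 fell in titled mutant (7 and 9 adjusted over the list alone), Peg10 (log2 -4.70) and the neuronatin gene Nnat (log2 -4.51) among those that fell and the cell cycle inhibitor Cdkn1c (log2 1.05) among those that rose, with a median of 0.06, a mean of -0.25 and a list test that pointed down (adjusted p = 0.55). Of 23 Notch genes 9 rose and 4 fell (12 and 5 adjusted over the list alone), the ligand Jag1 at log2 1.27 and the fringe gene Mfng at log2 -2.12 (list adjusted p = 0.064). Of 27 duct and trunk genes 9 rose and 3 fell (12 and 3 adjusted over the list alone), Krt7 at log2 -1.37 (SE 0.21), Clu at log2 0.94 (SE 0.19) and Sox9 at log2 0.66 (SE 0.21; list adjusted p = 0.064). Of 13 genes of cell cycle exit 5 rose and 5 fell (5 and 6 adjusted over the list alone), Gadd45a at log2 -2.95 (list adjusted p = 0.62).

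Metabolic and regulatory lists on ND were read next. Of 25 amino acid response genes 10 rose and 1 fell in titled mutant (11 and 1 adjusted over the list alone), the serine synthesis gene Phgdh at log2 1.82 (SE 0.30) and Sesn2 at log2 -1.90 (SE 0.20; list adjusted p = 0.016, and 0.67 with an estimated correlation). Of 36 nuclear respiratory genes 16 rose (22 adjusted over the list alone; adjusted p = 5e-05, and 0.35 with an estimated correlation), and of 31 genes of fatty acid oxidation 11 rose and 3 fell (13 and 3 adjusted over the list alone; adjusted p = 0.023, and 0.67 with an estimated correlation), Acaa2 at log2 1.17 (SE 0.18). Of 17 tested hypothalamic genes 2 rose and 11 fell (3 and 11 adjusted over the list alone; adjusted p = 0.0038, and 0.27 with an estimated correlation). Counts up and down were 8 and 3 of 23 for protein folding (9 and 3 adjusted over the list alone), 6 and 2 of 28 for lipid synthesis (6 and 2), 8 and 4 of 25 for antioxidant genes (9 and 4), 4 and 10 of 26 for chromatin regulators (5 and 10), with Hdac6 at log2 -1.82, 6 and 5 of 26 for insulin and mTOR signalling (6 and 5), and 3 and 2 of 25 for genes that dissociation induces (3 and 1), with list adjusted p = 0.10, 0.13, 0.16, 0.27, 0.48 and 0.64. Mitochondrially encoded genes had a median of -0.28, with 0 of 13 passing by edgeR (0 adjusted over the list alone; list adjusted p = 0.48).

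Markers of other cells were read beside these. On ND the medians were 0.77 for mesenchyme, -0.38 for blood and immune cells, 0.48 for neural crest and glia and -0.55 for 4 male-linked genes (list adjusted p = 0.12, 0.64, 0.64 and 0.064). All 4 male-linked genes reach at least 1 CPM in every library, as do 12 of 23 mesenchyme, 11 of 14 endothelial, 14 of 18 blood and immune, 4 of 15 neural crest and 19 of 25 acinar genes, and 1 mesenchyme gene also belongs to another list. The male-linked list had medians of -0.54 for genotype on HFD (adjusted p = 0.013, and 0.52 with an estimated correlation) and 0.59 for LPD in titled mutant (adjusted p = 0.00067, and 0.65 with an estimated correlation). The labels give both sexes as pooled, while Xist ran from 26.03 to 959.3 and Eif2s3y from 1.74 to 11.1 CPM of total over the mutant ND libraries. Both lows are in mutant ND 2, where Gm26917 takes 66.95% of counts and the TMM factor is 0.381. A scaling of that size is too small to account for the range of Xist. The share of each sex was not tested.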
